A study of Rattus norvegicus with 9 samples.

How the data were processed

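RNA sequencing was done on dorsal hippocampus from 9 male Sprague-Dawley rats, 4 with control rearing and 5 with early-life adversity (ELA). Per the labels' protocols, total RNA was isolated with a column kit, messenger RNA was selected by its poly(A) tail, and libraries were made with the Illumina TruSeq v2 kit and quantified by qPCR. The authors deposited 1 file of raw read counts per rat, with whole-number counts for 32545 rat Ensembl gene identifiers. Per the submitters' processing notes, reads were aligned with STAR 2.5.0 and counted with HTSeq 0.6.1, and the genome build was rn6. The annotation release, the strand setting of the counting and any read filters are not given in the sources used here. Reads of overlapping or antisense genes may therefore be joined or lost, and genes with near-identical copies lose the reads that align to several places.

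Each deposited count file ends with 5 summary entries that name no gene. They were kept out of library sizes and tests. Reads outside annotated genes took 15.18 to 18.14% of the records in a file, reads that matched more than 1 gene 1.57 to 1.8%, and reads aligned to several places 14.32 to 21.06%. The remaining 61.92 to 65.74% were assigned to genes, 11049282 to 17089188 reads per library. Groups came from the sample titles. No 2 libraries matched within sampling noise: over genes with at least 20 reads in a pair, the chi-square per degree of freedom was 3.93 to 21.9 over the pairs of libraries, so all 9 were kept as separate replicates. The labels give no sequencing batch or litter.

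The count files hold no gene symbols or coordinates. The gene table used here for names lists 47357 rat genes of another assembly and holds 0 Ensembl identifiers, so 0 of the 32545 identifiers could be matched. Before the data were examined, 35 gene lists (cell type markers, synaptic, stress hormone, inflammatory and metabolic genes), list tests with camera and a rule naming up to 12 genes with a symbol per direction had been fixed. None of these could be run without symbols, nor could checks of gene length or GC content. The printed identifiers follow the order of that rule, limited to 2 per direction: called genes with a mean CPM of at least 1 and no overlap of the groups, largest log2 fold change first, filled up by the smallest p-value among genes with a mean CPM of at least 1.

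Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the rearing groups, which left 14463 genes holding 99.91% of gene counts. Libraries were scaled by TMM, and the groups were compared by the robust quasi-likelihood test over all 9 libraries with no covariate. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its absolute value divided by the square root of the F statistic, and 95% intervals used the test's total degrees of freedom. Depth limits these errors most in genes of low expression. Principal components and distances between libraries used log2 CPM with a prior count of 2. Group differences of single values were tested by permuting the group labels over all assignments of the libraries, for which the smallest exact p is 0.0079.

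The edgeR step was tested on simulated data for this comparison, with counts drawn from the real means, library sizes and dispersions and 200 genes changed by known factors. Over the 14378 genes that this step tested, it recovered 26% of genes changed 1.25-fold, 64% of those changed 1.5-fold, 84% of those changed 2-fold and 94% of those changed 3-fold, each out of 50. It made 9 false calls among 143, and 0 calls when no gene was changed. On the same simulated counts DESeq2 made 19 false calls among 166, and 2 calls when no gene was changed. Limma-voom with sample weights made 5 false calls among 135, and 0 calls when no gene was changed. Each gene was drawn independently, so the simulated libraries held no variation shared across genes and no outlying library. These rates may therefore not carry over to the real libraries.

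The alternatives were DESeq2 size factors, upper quartile or no scaling factors, no filter, a filter on mean CPM, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1) with sample weights, the fit without robust estimation, an adjusted p under 0.1, 1 surrogate variable from sva 3.50.0, blocks by number, and leaving out each library in turn. The DESeq2 test on the genes tested by edgeR and limma-voom with equal weights were added after the data had been seen. Control and ELA libraries share numbers in 2 ways, in their titles and in their descriptions, and the labels do not say what either number means. No block was used in the main test.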

Results

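Messenger RNA was profiled by sequencing in the dorsal hippocampus of male Sprague-Dawley rats at 8 weeks of age. The hippocampus is the brain region that supports spatial and episodic memory, and Sprague-Dawley is an outbred laboratory stock. There were 4 rats from control rearing and 5 rats that had gone through early-life adversity (ELA), the general term for stressful conditions during infancy. The design text states that these animals had not taken part in behavioural tests. Each rat gave 1 library, so each replicate is a separate animal. The labels do not say which rats shared a litter, and the tests treated every rat as independent. Reads assigned to genes numbered 13652865 ± 711471 in the control libraries (SD, n = 4) and 13931388 ± 2326405 in the ELA libraries (SD, n = 5), and ranged from 11049282 in ELA replicate 4 to 17089188 in ELA replicate 1. Between 17989 and 18399 genes had at least 1 read in a library. The genes are identified by rat Ensembl identifiers only. None of the sources used here pairs these identifiers with gene symbols or positions, so the genes are given without a name, a location or a known function, and no gene group or cell type marker could be read.

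The comparison asked which hippocampal transcripts differed in adult rats with a history of adversity. Few genes passed the test. Of 14463 genes tested, 1 was higher and 5 were lower in the ELA rats at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). In each of these 6 genes, the 5 ELA rats lay wholly above or wholly below the 4 control rats. The gene with the smallest p-value, ENSRNOG00000010911, was expressed at 7.64 ± 0.998 CPM (the gene's reads scaled to library size) in control rats and at 17.1 ± 0.531 CPM in ELA rats (SD, n = 4 and 5). This was a 2.23-fold rise, a log2 fold change of 1.16 with a standard error of 0.095 and an adjusted p of 0.000351 by edgeR. ENSRNOG00000008138 fell in the ELA rats, from 10.6 ± 0.761 to 5.18 ± 0.583 CPM, a log2 fold change of -1.03 with a standard error of 0.108 (edgeR, adjusted p = 0.00282). These 2 genes were represented by 49 to 300 reads per library.

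The remaining 4 called genes were lower in the ELA rats by smaller factors, between 1.26-fold and 1.37-fold. ENSRNOG00000060348 had the largest of these changes and fell from 40.4 ± 2.09 to 29.4 ± 1.82 CPM (log2 fold change -0.46, standard error 0.065, edgeR adjusted p = 0.0299). This call did not hold (edgeR adjusted p from 0.0621 to 0.217) without any 1 of control replicates 2, 3 and 4 or of ELA replicates 1, 2, 3 and 4, although the log2 fold change stayed between -0.48 and -0.42 in these fits. Among genes higher in the ELA rats, the one with the next smallest p-value after ENSRNOG00000010911 was ENSRNOG00000023077, which did not pass the threshold. It was at 2.77 ± 0.732 CPM in controls and 6.79 ± 1.82 CPM in ELA rats, with a log2 fold change of 1.29, a standard error of 0.23 and an edgeR adjusted p of 0.127. It passed in the fits without control replicate 1 (edgeR adjusted p = 0.0282) and without ELA replicate 5 (edgeR adjusted p = 0.0439).

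**Figure D1:**
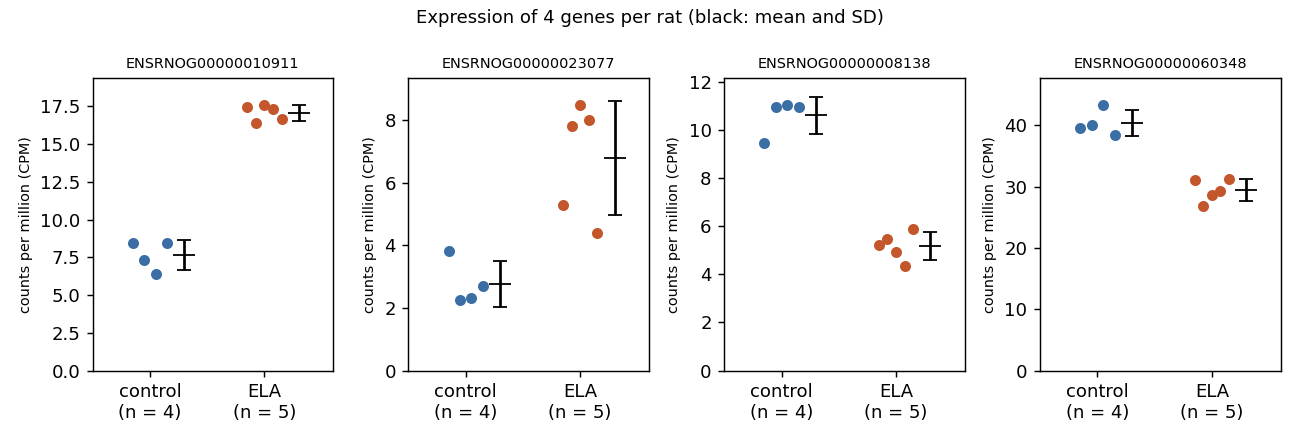
Expression in CPM (vertical axes, each starting at 0) of 4 genes in control and ELA rats, with 1 point per rat and the mean and SD in black beside each group. In all 4 genes the ELA rats do not overlap the controls. For the called genes this was part of the rule that picked them. ENSRNOG00000023077 was picked by its p-value and did not pass the adjusted test (edgeR adjusted p = 0.127). Groups without overlap were found in 3.04% of the genes tested, against 1.59% by chance.

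Below the threshold, more genes had small p-values than uniform p-values would give. An unadjusted p under 0.05 was found for 1360 genes, against 723 expected if no gene differed. They were split evenly, with 679 higher and 681 lower in ELA rats. With libraries scaled by total counts only, 599 were higher and 750 lower. Groups that did not overlap were found in 439 genes, 201 higher and 238 lower in ELA rats, which is 3.04% of the genes tested against 1.59% by chance. Neither excess was compared with that in other groupings of the libraries. Genes that vary together can move such shares away from the expected ones in any grouping, so the excesses are not assigned to rearing. Both excesses changed when single libraries of either group were left out. Without control replicate 3, an unadjusted p under 0.05 was found for 357 higher and 459 lower genes, and the share without overlap was 1.12 times that by chance, compared with 1.91 times with every library. Without control replicate 4 these values were 425, 528 and 1.22, and without control replicate 1 they rose to 1059, 870 and 2.58. With 1 ELA library left out the share without overlap was 1.35 (without ELA replicate 3) to 2.05 (without ELA replicate 4) times that by chance. The genes with an unadjusted p under 0.05 then ran from 464 higher and 548 lower (without ELA replicate 2) to 899 and 976 (without ELA replicate 4). The excess was smallest among genes of low expression. With the genes divided into 3 sets of 4821 by mean expression, 7.49% had an unadjusted p under 0.05 in the lowest set, compared with 9.85% in the middle set and 10.9% in the highest set. The median standard error of the log2 fold change was 0.193, 0.088 and 0.0646 in these sets.

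With all 9 libraries in the groups their labels give, large differences were excluded for most genes taken singly. The 95% interval of the log2 fold change lay within a 2-fold change in either direction for 13772 of the 14463 genes (95.22%), and within a 1.5-fold change for 11588 genes (80.12%). Without control replicate 1 these shares were 92.78% and 75.78% of 14561 genes. These intervals are per gene and are not adjusted for the number of genes. The median absolute log2 fold change was 0.0802 and the median standard error was 0.0967. The first would lie below the second even if no gene differed, so their order does not show that differences were absent. The biological coefficient of variation between rats of one group was 9.74%.

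The number of called genes depended on control replicate 1. Without this library, 50 genes were higher and 80 were lower in ELA rats, 130 in all, and these included all 6 genes called with every library. With 1 of the other 8 libraries left out, 2 genes were called (without control replicate 2, 3 or 4), 3 (without ELA replicate 1, 3 or 4), 4 (without ELA replicate 2) or 6 (without ELA replicate 5). ENSRNOG00000010911 and ENSRNOG00000008138 passed the threshold in each of these 9 fits by edgeR, with adjusted p-values of at most 0.00485 and 0.0285. With a block by title number, only ENSRNOG00000010911 was called. ENSRNOG00000008138 then had an edgeR adjusted p of 0.0602 at a log2 fold change of -1.08, against -1.03 with no block. Blocks take up degrees of freedom, and the ELA library without a control of its number adds nothing to the group difference. A lost call therefore need not mean a smaller difference. A block by description number gave 29 genes higher and 49 lower, with all 6 genes among them. Other tools also gave other counts. On the same libraries the DESeq2 Wald test, with its own filter, called 35 genes higher and 107 lower, and without that filter on the genes tested by edgeR it called 35 and 105. Limma-voom called 143 higher and 162 lower with sample weights, but 1 higher and 5 lower with equal weights. Each of these 4 fits included the 6 genes called by edgeR.

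**Figure D2:**
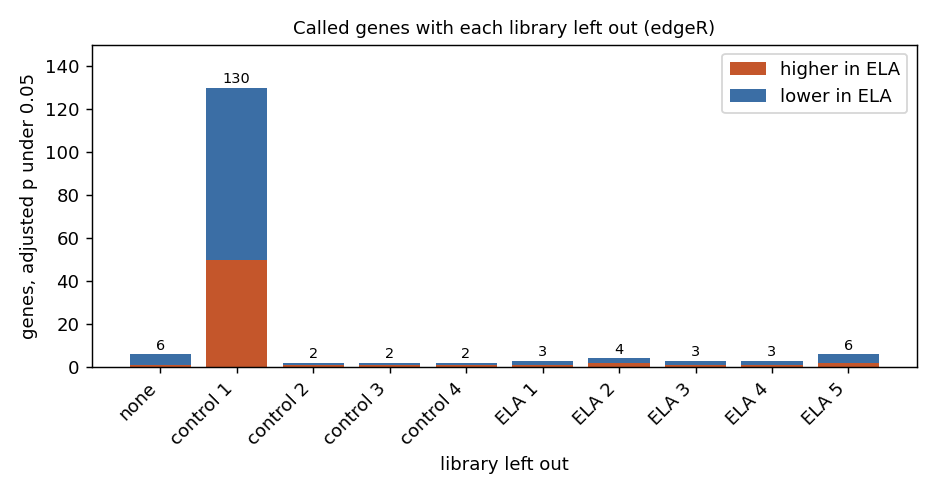
Number of genes with an adjusted p under 0.05 (vertical axis) in edgeR fits with no library or 1 library left out (horizontal axis), split into genes higher and lower in ELA rats. The fit without control replicate 1 gives 130 genes, and the other fits give 2 to 6.

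In a test of the overall expression profiles the rearing groups did not separate past the threshold. The first principal component of the 500 most variable genes held 33.9% of their variance. Its mean score was 6.1 ± 7.92 in control rats and -4.88 ± 6.51 in ELA rats (SD, n = 4 and 5), a difference that did not pass an exact permutation test (two-sided p = 0.0635 over all assignments of the libraries, 0.19 after adjustment over 3 components). Control replicates 2, 3 and 4 scored between 7.62 and 12.84, above every ELA rat. Control replicate 1 scored -5.31, between ELA replicates 1 and 2 at -4.79 and -9.96. Without control replicate 1 the difference was larger (exact permutation two-sided p = 0.0357, or 0.107 after adjustment over 3 components). The other 2 components tested did not pass either (exact permutation p = 0.833 and 0.127).

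**Figure D3:**
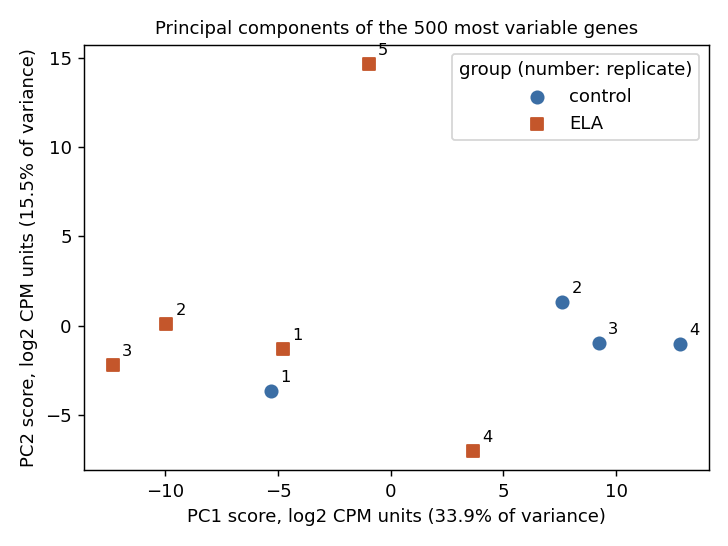
Scores of the 9 libraries on the first and second principal components of log2 CPM over the 500 most variable genes (axes in log2 CPM units), with circles for control rats, squares for ELA rats and numbers for replicates. Control replicates 2 to 4 lie to the right, and control replicate 1 lies at -5.31 among the ELA rats.

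The spread between rats of one group was compared as the distance between their libraries. The mean distance between libraries, the root mean square difference of log2 CPM over tested genes, was 0.342 within ELA and 0.303 within control. The difference of 0.0393 did not pass an exact permutation test (two-sided p = 0.0794). The difference passed without control replicate 1 (0.0702, exact permutation p = 0.0179, the smallest this fit can give) and without ELA replicate 1 (0.0548, exact permutation p = 0.0286). Control replicate 1 was the control farthest from the others (mean distance 0.334, against 0.291 to 0.295), so leaving it out lowers the control spread. The groups were not centred before permuting, so a difference between the group means can also move these p-values. The difference was 0.0195 without ELA replicate 4. The distance between rats of different groups averaged 0.342, which exceeded the mean of the within-group distances by 0.0194 (one-sided exact permutation p = 0.0873). The library nearest to control replicate 1 was ELA replicate 1, at 0.272, and the reverse also held. Control replicates 2, 3 and 4 each had another control as nearest library. ELA replicates 4 and 5 had control replicates 4 and 2 as nearest library.

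The read assignment of the libraries did not differ detectably by rearing. Reads aligned to several places made up 17.0 ± 1.93% of the records in control files and 18.75 ± 1.71% in ELA files (SD, n = 4 and 5, exact permutation p = 0.206). Reads outside annotated genes made up 16.96 ± 0.81% and 16.24 ± 0.621% (exact permutation p = 0.206). The 10 most abundant genes took 7.2 ± 0.747% and 7.03 ± 1.13% of gene counts (exact permutation p = 0.817). Over the 7 library measures compared, the smallest adjusted p was 0.574 by the exact permutation test.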

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

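The comparisons with library measures, the test of an axis of variation present in both groups, the positions over the 100 and the 6 genes with the smallest p-values and the reading of distances between libraries were chosen only after results had been seen, and the test of a wrong label over the 130 genes was set before its value was computed but after the number of genes without each library was known. Single libraries that stood apart from their group were sought by Dixon's ratio in 28 sets of values, of which chance would flag about 1 in 20, and 2 were found. ELA replicate 5 had 15.18% of reads outside annotated genes, against 16.31 to 16.77% in the other ELA libraries. Control replicate 1 had 9.47 CPM of ENSRNOG00000008138, against 10.96 to 11.04 CPM in the other controls, and remained above every ELA library.

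The number of called genes rose from 6 to 130 without control replicate 1. Depth or read assignment gave no sign of a failed library, since 0 of 5 measures of control replicate 1 lay outside the range of the other 8 libraries. Whether a mislabelled library may be the cause was not decided. Over the 130 genes called without control replicate 1, its median position between the other controls (0) and the ELA rats (1) was 0.764. The quartiles were 0.524 and 1.02. This median passed the bound set beforehand as a mark of a wrong label. However, 124 of these genes were not called with control replicate 1, so its position largely restates the pattern. A second condition, on the 6 genes with the smallest p-values, was added after results had been seen, and control replicate 1 did not meet it. Over the 100 genes with the smallest p-values in the fit without the library in question, control replicate 1 stood at 0.747. The other controls stood at -0.245 to 0.198 and the ELA rats at 0.522 to 1.17. Of the 6 genes with the smallest p-values in that fit, 3 put control replicate 1 below 0.25 (0.169 to 0.221, among them ENSRNOG00000010911) and 3 above 0.9 (0.982 to 1.42). Each of the other controls had 5 or 6 such genes below 0.25 and 0 above 0.9, and the ELA rats had 0 or 1 below 0.25 and 2 to 6 above 0.9. Over these 6 genes control replicate 1 thus matched neither group, while over the 100 genes it lay within the range of the ELA rats. The fits without another library called only 2 to 6 genes and kept control replicate 1 among the controls. Positions from them are therefore not a like-for-like reference for control replicate 1. An axis of variation present in both rearing groups is a candidate explanation too: across genes, which are not independent replicates, the departure of control replicate 1 from the other controls followed the first component among ELA rats alone (r = 0.481, against 0.0212 to 0.0719 in size for departures among the other 3 controls alone). With control replicate 1 in their reference, the other controls gave -0.141 to -0.245, values that centring ties to its own. This test does not separate such an axis from a wrong label. In the chi-square per degree of freedom between the counts of 2 libraries, control replicate 1 was at 4.07 to 5.15 with ELA replicates 1 to 3. It was at 10.1 to 11.6 with the other controls and at 13.1 to 14.8 with ELA replicates 4 and 5. By distance in log2 CPM, control replicate 1 averaged 0.317 to all ELA rats and 0.334 to the other controls. In chi-square, ELA replicates 4 and 5 were at 7.62 to 10.7 with control replicates 2 to 4 and at 12.8 to 21.9 with ELA replicates 1 to 3. A wrong label of control replicate 1 alone leaves the place of ELA replicates 4 and 5 unaccounted for, but both explanations stay open, and individual biological differences were not tested. Batch and litter could not be examined either, since the labels do not give them.

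The first principal component, along which control replicate 1 lies with the ELA rats, was set against 7 library measures over the 9 libraries, and none of the 7 relations passed after adjustment (smallest adjusted exact permutation p 0.416 for Pearson's r and 0.258 for Spearman's rho). Depth (r = -0.253, exact permutation p = 0.522) and the number of genes with a count (r = 0.318, exact permutation p = 0.393) stayed under 0.5 in size with any 1 library left out. This bound was set after results had been seen, and r is imprecise over 9 libraries. It is therefore only weak evidence against these 2 measures as the whole source, and none against a part. Their rho was -0.333 and 0.283 (exact permutation p = 0.385 and 0.463). Without the 2 libraries farthest from the median of the measure, their r was -0.0879 and 0.0673. The share of reads assigned to genes had r = -0.0336 (exact permutation p = 0.929) and rho = -0.0667 (exact permutation p = 0.88). Its r ran from -0.495 to 0.119 with 1 library left out and was -0.434 without the 2 farthest. This is under 0.5 in size too, but close to it, so this share decides nothing. The share of counts in the 10 most abundant genes followed the component most closely, with r = 0.579 (exact permutation p = 0.103), rho = 0.717 (exact permutation p = 0.0369), r = 0.766 without the 2 farthest libraries and 0.442 to 0.832 with 1 left out, and it stays open with the share of reads overlapping several genes (r = 0.558, exact permutation p = 0.119; rho = 0.483, exact permutation p = 0.194; r = 0.377 without the 2 farthest). The shares of reads aligned to several places (r = -0.148, exact permutation p = 0.709; rho = 0.05, exact permutation p = 0.912) and outside annotated genes (r = 0.371, exact permutation p = 0.345; rho = 0.142, exact permutation p = 0.717) changed sign without the 2 farthest libraries (r = 0.564 and -0.181), so these relations rest on those libraries and decide nothing. Differences in dissection or cell composition could not be examined without gene names.

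The real grouping was set beside other groupings of the same libraries, 100 of those possible, the real one included. For genes higher in ELA (1 gene), 5 of the 100 splits gave as many, so chance could not be excluded for this number. Such a count does not test the gene itself. For genes lower in ELA (5 genes), 4 of the 100 splits gave as many, a share under 0.05. Not all groupings were run, so both shares are estimates, and both lie close to 0.05. Among the splits run, the highest other count was 388 higher and 298 lower genes, 686 in all. That split exchanged control replicate 1 with ELA replicate 4. The split that exchanged it with ELA replicate 5 gave 251 genes. These counts, many times the real 6, point to a structure among the samples that the rearing groups do not follow. Of the 100 splits, 93 called 0 genes. Control replicate 1 with the ELA libraries other than replicates 4 and 5, its nearest by chi-square, was not among the splits run. A count above 686 is therefore not excluded.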

How the results depend on the processing

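The DESeq2 test on the genes tested by edgeR and limma-voom with equal weights were chosen after the data had been seen. Scaling by DESeq2 size factors, upper quartile or total counts, the filter on mean CPM and the fit without robust estimation each gave 1 gene higher and 5 lower in ELA rats, the same 6 genes. Without a low-count filter 2 were higher and 9 lower. An adjusted p under 0.1 gave 1 and 6, and 1 surrogate variable 1 and 7. The DESeq2 Wald test gave 35 higher and 107 lower, or 35 and 105 without its own filter on the genes tested by edgeR. Limma-voom gave 143 and 162 with sample weights, and with equal weights 1 and 5, the same 6 genes as edgeR. Of the 142 genes of DESeq2 and 305 of weighted limma-voom, 73 and 116 were among the 130 called by edgeR without control replicate 1. The cause of the DESeq2 difference was not tested. The weights were 0.494, 0.613 and 0.989 for ELA replicates 4, 5 and 3, 0.644 for control replicate 1 and 1.22 to 1.64 for the others. Leaving out 1 library gave 1 to 50 genes higher and 1 to 80 lower, the highest values without control replicate 1. The replicate block by title number gave 1 higher and 0 lower. The replicate block by description number gave 29 higher and 49 lower. Deviations of same-numbered libraries correlated at -0.129 to 0.241 by title and -0.172 to 0.244 by description, so neither number was taken as a pairing. The group difference on the first principal component ranged from -15.4 to -9.18 with 1 library left out, past 0.05 without control replicate 1 only (exact permutation p = 0.0357, adjusted 0.107). It was -14.8 over all tested genes (exact permutation p = 0.19). The difference in within-group distance ranged from 0.0195 to 0.0702 with 1 library left out. The log2 fold change of ENSRNOG00000010911 was 1.08 to 1.21 over 22 alternatives, past the threshold in all 22 (adjusted p from 4.55e-20 to 0.0145), and that of ENSRNOG00000008138 was -1.08 to -0.98, past it in 21 (highest adjusted p 0.0602, with the title block). The call of ENSRNOG00000060348 held in 14 of 22 (log2 fold change -0.48 to -0.42, adjusted p from 6.19e-06 to 0.217), and ENSRNOG00000023077 was called in 7 of 22. The fold changes of the printed genes and the 2 group differences kept their sign, while the balance of higher and lower genes turned in some fits, from 679 and 681 at an unadjusted p under 0.05 to 1059 and 870 without control replicate 1. Covariates for choroid plexus and myelin genes, the components without listed genes, and all list tests were not run, since no identifier could be matched to a symbol.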
